A study of Homo sapiens with 12 samples.

How the data were processed

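Small RNA was sequenced in 12 libraries of HCT116 cells by AQ-seq, and the libraries were grouped by the rescue DICER named in the labels: WT, E5, A5, ΔPAZ helix, R821E and R821A, 2 libraries each. Per the labels' protocols, RNA was extracted with TRIzol, the libraries were amplified with a Q5 polymerase mix and sequencing was done on a NovaSeq 6000. The values deposited by the authors are raw counts per entry, whole numbers with no normalisation. The submitters' processing notes name cutadapt, BWA and bedtools and the builds hg38 and mm10, while their versions, the role of each build, and how reads matching several miRNAs were counted are not given in the sources used here. Reads that match near-identical miRNAs could have been counted for several entries or divided between them: miR-500a-5p and miR-500b-5p have identical counts in every library (1 such pair among tested entries), and members of the let-7 family are reported as uncertain singly.

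The tables held 1376 entries, of which 1346 were miRNAs (547 named 5p, 513 named 3p, 286 with no arm in the name) and 30 were spike-in sequences. Spike-in entries were kept out of library sizes and tests. They took 3.99% ± 0.395 of all counts in WT (SD, n = 2), 5.52% ± 0.261 in E5, 5.13% ± 0.0542 in A5, 4.97% ± 0.472 in ΔPAZ helix, 6.54% ± 0.589 in R821E and 4.91% ± 0.653 in R821A. Total miRNA counts of replicates 1 and 2 were 250755 and 247226 in WT, 179615 and 227199 in E5, 193950 and 250294 in A5, 224548 and 183673 in ΔPAZ helix, 229302 and 144067 in R821E, and 255296 and 206580 in R821A. At these depths 3 counts correspond to 11.8 to 20.8 counts scaled to library size (CPM), a limit for counting error only, since PCR reads without molecular identifiers are not independent molecules. Replicates were checked for duplicated libraries: the chi-square of their counts per degree of freedom was 3.98 to 29.4, above sampling noise in every group, so no library was a copy of its partner. This does not show that partners came from separate RNA, and the libraries were counted as separate samples because the labels list them so.

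Counts were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood test with robust empirical Bayes, TMM factors, filterByExpr by group) in a single fit over all 12 libraries, which leaves 6 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The filter left 374 entries (174 5p, 148 3p, 52 without an arm) with 99.6% of miRNA counts. Each mutant was compared with WT, E5 with A5 and R821E with R821A. The ratio of arms was tested with limma 3.58.1 (trend and robust) on log2 of (5p + 0.5)/(3p + 0.5) for the 65 hairpins with a mean of at least 20 counts in both arms. Lists of miRNAs were tested with camera (preset correlation 0.01, at least 3 tested members), and with an estimated correlation and fry as alternatives. The lists were the let-7 family and its groups I and II, the miR-17~92, miR-200, miR-15/16, miR-34, miR-30, miR-29, miR-10/99/100, miR-232724, miR-221/222, miR-181 and miR-320 families, the intestinal miR-192/194/215, the miR-371~373 and miR-302 clusters, mirtrons, hairpins that begin at a transcription start site, the DICER-independent miR-451a, entries overlapping snoRNA, tRNA or rRNA, and miRNAs of erythroid cells, leukocytes, muscle, neurons, hepatocytes, and fibroblasts with endothelium. None of the camera calls on a list held with an estimated correlation. Correlations of fold changes between mutants were set beside 100 simulations of unchanged groups, in which all 12 libraries were drawn anew. In each simulation the mutants shared the drawn WT libraries, so deviations of the measured WT libraries are not in it. Calls that recur between mutants were set beside 100 such simulations from which lists of the observed lengths were taken, a comparison chosen after seeing the data. For called entries with at most 3 counts per library on average in a group, the ratio of summed counts is given with an exact (Clopper-Pearson) interval in place of a fitted fold. This interval holds counting error only and leaves out the spread between replicates. It can therefore be too narrow for the difference between groups. Single values per library were compared by exact permutation.

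The groups, comparisons, tests, lists and rule for named entries were chosen before the data were examined. By that rule, the text names for each mutant the 10 largest rises and 10 largest falls among called entries with a mean of at least 100 CPM in either group and both mutant libraries on the same side of both WT libraries, the 5 entries highest in WT, list members as examples, 5 entries each way for a direct comparison and 5 hairpins each way for the arm ratio. Alternatives chosen beforehand were DESeq2 1.42.0, limma-voom, the DESeq2 size factors, upper quartile factors, total counts, no filter, a mean of at least 100 CPM, only the 4 libraries compared, the replicate number as a block, no robust step, a fold of at least 2, other count minimums and a pseudocount of 5 for the arm ratio, and leaving out each library. Alternatives added after seeing the data were the spike-in scale (summed counts of the 29 spike-in sequences with a mean of at least 50, with or without their own TMM factor), leaving out miR-21-5p or the entries without an arm, a count minimum on the weaker arm in WT, and crossed replicate numbers. A TMM scale reports changes relative to the bulk of miRNAs, so a loss shared by most miRNAs does not show on it, whereas the spike-in scale depends on equal addition of spike-ins to equal amounts of RNA.

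On simulated counts with known changes for R821E against WT (374 entries), edgeR recovered 23.9% of 1.5-fold, 59.7% of 2-fold and 93.9% of 4-fold changes, with 3 false calls among 174 unchanged entries. For A5 against WT with no change it made 0 false calls of 374. The arm test recovered 5.0% of 2-fold and 92.5% of 4-fold shifts for R821E against WT (65 hairpins, 40 of them changed), with 0 and 2 false calls among the unchanged hairpins, so smaller shifts would mostly be missed. Locations were taken from GENCODE v29 on GRCh38, the same assembly as the hg38 named by the submitters' processing notes: 354 of the 374 tested entries matched an annotated miRNA gene by name, 318 of them a single locus. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.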

Results

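Mature miRNA levels were measured in HCT116 cells, a human colorectal carcinoma line, rescued with wild-type DICER or with a mutant DICER. DICER is the RNase III enzyme that removes the loop of a precursor hairpin and releases its 5p and 3p strands. The 12 libraries were made by AQ-seq, a small-RNA sequencing method designed to lower ligation bias, and fell into 6 groups of 2: wild type (WT), E5, A5, ΔPAZ helix, R821E and R821A. In R821E and R821A an arginine, R821 by the name of the mutants, is replaced by glutamate or by alanine, and ΔPAZ helix, by its name, lacks a helix of the PAZ domain. What E5 and A5 stand for is not given in the sources used here. The series concerns the structure of human DICER bound to a precursor in the act of cleavage, and each mutant was compared with WT to ask how the altered protein changes the miRNA output of cells. The libraries held 144067 to 255296 miRNA counts and 617 to 804 detected entries. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The edgeR fit shares its spread between groups, although WT replicates differed most, so its p-values against WT can be too small.

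miRNAs were fewer relative to the spike-in sequences in every mutant library than in either WT library. WT libraries held 24.2 ± 2.49 miRNA counts per spike-in count (SD, n = 2), against 17.1 ± 0.856 in E5, 18.5 ± 0.206 in A5, 19.2 ± 1.92 in ΔPAZ helix, 14.3 ± 1.38 in R821E and 19.6 ± 2.73 in R821A. All 10 mutant libraries lay below both WT libraries (two-sided exact permutation test over the 66 splits of 2 against 10 libraries, p = 0.0152, the smallest these splits allow). This test was chosen after the data were seen, and over the 10 library quantities compared in the same way the adjusted p was 0.152 (Benjamini-Hochberg, exact permutation tests). It shuffled single libraries, although they came as 6 groups of 2. Its p-values, here and for the shares and ratio below, are therefore too small where the 2 libraries of a group resemble each other. In an exact permutation test a single mutant against WT, 2 libraries against 2, cannot go below p = 0.333. R821E libraries stood farthest from WT in composition. The 3p strands made up 11.5% ± 0.590 of miRNA counts there and 26.2% ± 1.81 in WT, and miR-21-5p, an abundant oncogenic miRNA, made up 56.0% ± 2.84 and 40.4% ± 3.89. The ratio of 5p to 3p counts was 7.09 ± 0.509 in R821E and 2.64 ± 0.235 in WT. Over all 10 mutant libraries against WT, the same exact permutation test gave p = 0.106 for the 3p share, 0.227 for the miR-21-5p share and 0.258 for the ratio of 5p to 3p counts (adjusted p = 0.208, 0.253 and 0.258). In the other mutants the 3p share was 20.4% ± 2.23 (E5), 21.3% ± 1.44 (A5), 21.8% ± 1.42 (ΔPAZ helix) and 25.6% ± 2.28 (R821A). The amount of spike-in added and the step of its addition are not given in the sources used here.

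**Figure D1:**
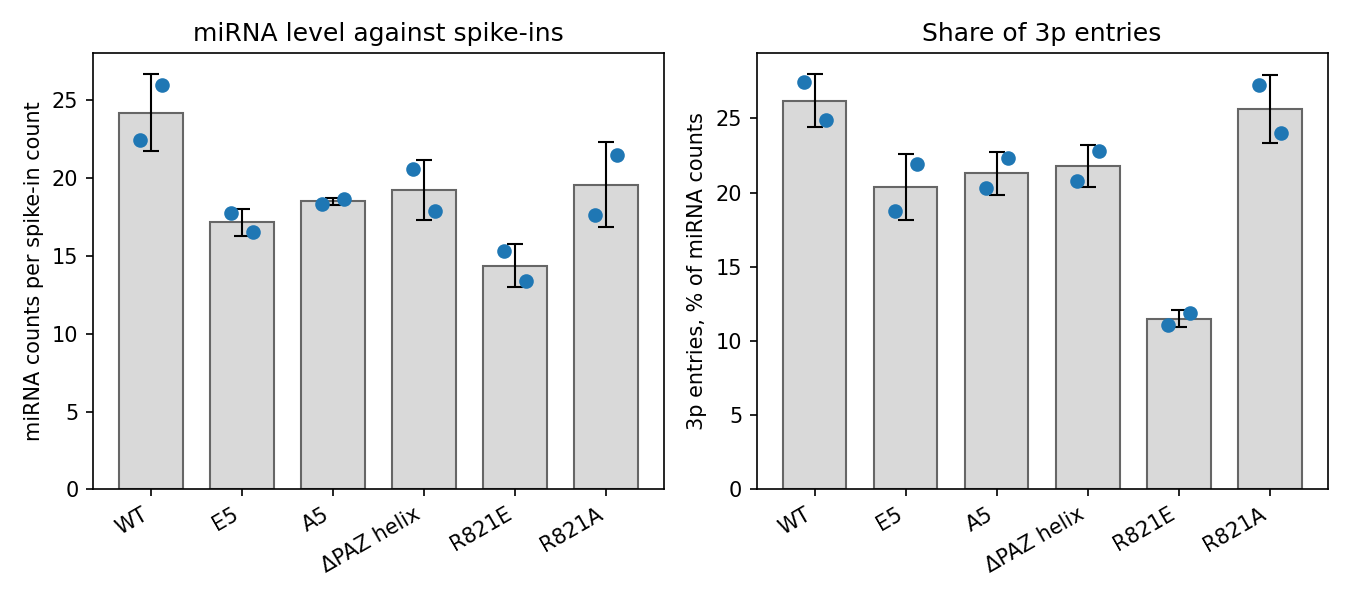
Left, miRNA counts per spike-in count; right, 3p entries as a percentage of miRNA counts; bars are means of 2 libraries per group, error bars are SD and points are libraries. All 10 mutant libraries lie below both WT libraries on the left, and R821E has the lowest 3p share, 11.5% on average.

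Because miRNA counts per spike-in count differed between groups, each comparison is given on 2 scales. The trimmed-mean (TMM) scale reports each miRNA relative to the bulk of the others, and the spike-in scale, chosen after the data were seen, reports it relative to the spike-ins. The median log2 fold change against WT on the spike-in scale was -0.61 in E5, -0.47 in A5, -0.36 in ΔPAZ helix, -1.35 in R821E and -0.28 in R821A. It was between -0.10 and 0.03 on the TMM scale. Below, "rose" and "fell" refer to the TMM scale, that is to a change relative to the other miRNAs, unless the spike-in scale is named. Named entries are those of a rule fixed before the data were examined, which takes entries with at least 100 CPM (counts scaled to library size) in either group, and orders of size refer to these unless another basis is given.

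R821E had the broadest effect. Of 374 miRNA entries tested, 89 rose and 90 fell relative to the others, while on the spike-in scale 223 were called, 99.6% of them lower. miR-25-3p, from the miR-106b~25 cluster, fell from 3778 ± 436 to 582 ± 24.8 CPM (SD, n = 2), a log2 fold change of -2.70 ± 0.162 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 7.16e-08). miR-185-5p fell by 2.96 ± 0.311 (adjusted p = 1.31e-05), from 562 ± 135 to 71.5 ± 2.91 CPM. miR-221-3p, a repressor of the cell-cycle inhibitor CDKN1B, fell by 1.60 ± 0.144 (adjusted p = 4.49e-06). miR-21-5p rose by 1.01 ± 0.159 on the TMM scale (adjusted p = 2.61e-04) but had a log2 fold change of -0.25 ± 0.193 on the spike-in scale (adjusted p = 0.278), so its rise was shown relative to the other miRNAs and not relative to the spike-ins. Next in size among the falls with at least 100 CPM in either group came miR-3187-3p, with 6 counts in R821E and 55 in WT (ratio 0.215, 95% exact counting interval 0.0756 to 0.499), miR-324-5p (-2.11), miR-193a-3p (-2.04), miR-107 (-1.95), miR-877-5p (-1.89), miR-1180-3p (-1.87), miR-99b-3p (-1.86) and miR-92b-3p (-1.83). Of the 5 most abundant WT entries, miR-222-3p (-0.92) and miR-27a-3p (-1.52) also fell, and miR-31-5p did not pass the test on the TMM scale (-0.34 ± 0.221, edgeR, adjusted p = 0.221) but was lower on the spike-in scale (-1.60, adjusted p = 1.40e-05).

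Among the rises in R821E with at least 100 CPM in either group, miR-8072 led. It rose by 2.47 ± 0.462 (adjusted p = 9.18e-04) and, alone among all tested entries, rose on the spike-in scale too (1.23 ± 0.465, adjusted p = 0.0351). miR-573 (1.96), miR-548b-5p (1.77), miR-4454 (1.66), miR-3687 (1.64), miR-128-1-5p (1.64), miR-4484 (1.58), miR-181b-3p (1.57), miR-1275 (1.52) and miR-3653-5p (1.48) followed, and none of these 9 passed the test on the spike-in scale. By strand, 50 5p entries rose and 28 fell, 18 3p entries rose and 56 fell, and 21 entries without an arm name rose and 6 fell (Fisher's exact test of 5p against 3p, two-sided, p = 8.44e-07, with entries not independent of each other). The median log2 fold change was 0.17 for 5p and -0.58 for 3p entries on the TMM scale, and -1.08 and -1.85 on the spike-in scale, so the 5p median flipped sign there and with total counts as the scale (-0.39). The 3p entries as a list lay below the other entries (camera, preset correlation, adjusted p = 1.89e-04), and this call was lost with an estimated correlation (adjusted p = 0.147 with an estimated correlation). With total counts as the scale, 40 entries rose and 148 fell, around a median of -0.65.

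**Figure D2:**
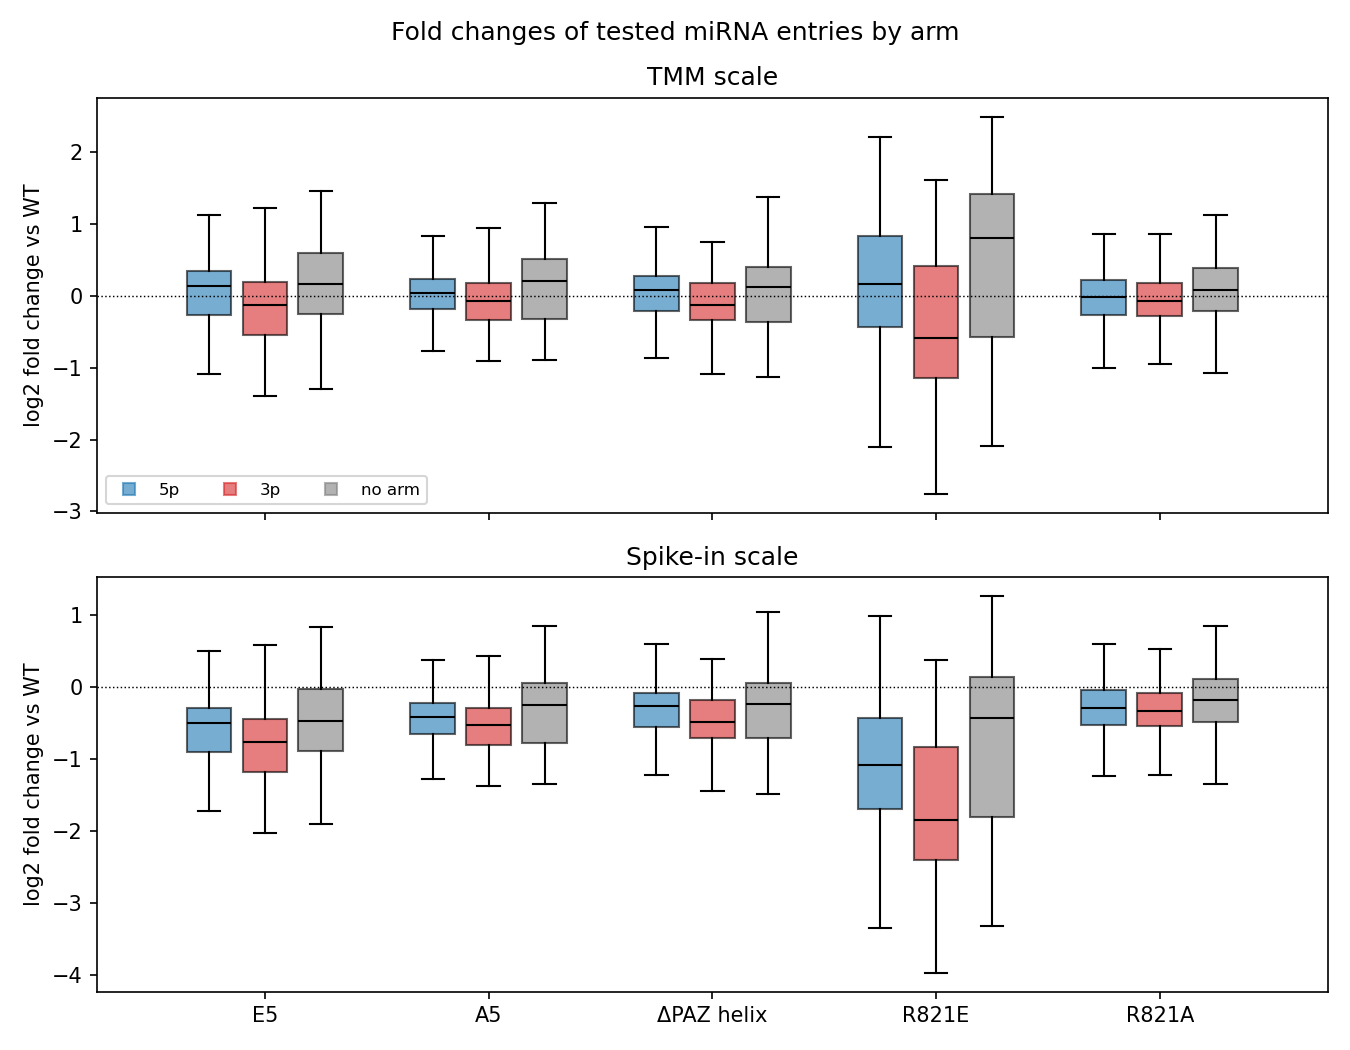
Log2 fold change against WT of the 374 tested entries, by mutant and by arm, on the TMM scale (top) and on the spike-in scale (bottom); boxes span the quartiles, lines are medians and whiskers leave out outliers, which are not drawn. In R821E the 3p median is -0.58 on the TMM scale and -1.85 on the spike-in scale, and the 5p median flips from 0.17 to -1.08.

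Families fixed beforehand divided in R821E. Of 11 tested members of the miR-15/16 family, regulators of BCL2 and of cyclins, 7 rose and none fell, such as miR-16-5p (0.67) and miR-15a-5p (1.01), though the family median of 0.67 flipped to -0.59 on the spike-in scale. In the miR-181 family 5 of 7 rose and none fell, with a median of 0.80 that flipped to -0.47 on the spike-in scale. The list of miR-221 and miR-222 had 3 of 4 members lower and none higher, with a median of -0.69 (-1.95 on the spike-in scale). The miR-232724 clusters had 5 lower and 2 higher of 11, with 27a-3p, 27b-3p, 23a-3p, 23b-3p and 24-3p lower, and a median of -0.05 that was positive (0.02) only with the DESeq2 size factors. Both arms of the mirtron miR-877, whose hairpin is made by splicing without DROSHA, fell. The log2 fold change of miR-877-5p was -1.89, and miR-877-3p went from 54 counts in WT to 4 in R821E (ratio 0.146, 95% exact counting interval 0.0384 to 0.396). miR-320a (-1.07) and miR-484 (-0.93), whose hairpins begin at a transcription start site, fell too. miR-451a, matured by AGO2 without DICER, rose by 1.00 ± 0.267 relative to the others (adjusted p = 0.00753, edgeR), and its log2 fold change on the spike-in scale was -0.26. Of the 9 tested entries that overlap snoRNA, tRNA or rRNA, 5 rose and none fell, with a median of 1.18 on the TMM scale and -0.07 on the spike-in scale. No family passed camera in R821E (lowest adjusted p, 0.0628, for these 9 entries), whereas 11 lists passed fry, which asks only whether a list's members move on balance to one side.

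Mixed counts were seen in the remaining families of R821E. They were 3 higher and 8 lower of 19 in the let-7 family, 2 and 6 of 13 in its group II, whose precursors are mono-uridylated before dicing, and 0 and 1 of 3 in its group I. The higher and lower counts were 6 and 5 of 20 in the miR-17~92 and paralogous clusters, 2 and 3 of 6 in the epithelial miR-200 family, 2 and 3 of 10 in the miR-30 family, 3 and 2 of 7 in the miR-29 family, 4 and 2 of 7 in the miR-10/99/100 family, 0 and 1 of 3 in the miR-320 family and 0 and 0 of 3 in the miR-34 family. miR-194-5p fell (-1.52) and miR-192-5p did not pass (0.46) in the intestinal list. Adjusted over the list alone, the counts were 4 and 3 for miR-30 and 1 and 3 for the list of miR-221 and miR-222, and those of the other families named for R821E did not differ from the counts given.

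The 5p to 3p ratio of single hairpins shifted toward 5p in R821E. Among 65 hairpins with both arms measured, 28 shifted toward 5p and 9 toward 3p, with a median log2 shift of 0.54, and 9 hairpins exchanged their dominant arm. miR-221 shifted by 3.56 ± 0.653 (SE; limma, adjusted p = 0.00245), from a log2 5p/3p ratio of -2.49 ± 1.24 in WT to 1.07 ± 0.0155 in R821E, and miR-200a (3.02), miR-454 (2.83), miR-331 (2.55) and miR-27a (2.40) followed. The largest shifts toward 3p were in miR-26b (-2.07 ± 0.502, limma, adjusted p = 0.00875), miR-96 (-1.58), let-7b (-1.20), let-7g (-1.14) and miR-324 (-1.01). None of these 5 passed without WT replicate 1, and of them miR-324 alone passed without R821E replicate 2. Of 22 hairpins led by the 3p arm in WT, 16 shifted toward 5p and 0 toward 3p, and of 43 led by the 5p arm, 12 shifted toward 5p and 9 toward 3p. The same WT libraries sort the hairpins and enter the shift, so part of this contrast is built in. Scaling cancels in the 5p to 3p ratio. The count of 37 shifts became 19 without WT replicate 1, 18 without R821E replicate 2, 24 when only the 4 libraries compared were fitted and 9 among the 13 hairpins with at least 100 counts in both arms. Across the 65 hairpins the fold changes of the 2 arms had Pearson's r = 0.16 and Spearman's rho = 0.08 in R821E, and r was 0.34, 0.04, 0.11 and 0.24 in E5, A5, ΔPAZ helix and R821A; these 5 relations describe hairpins, which are not independent replicates, and no p-value was computed.

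**Figure D3:**
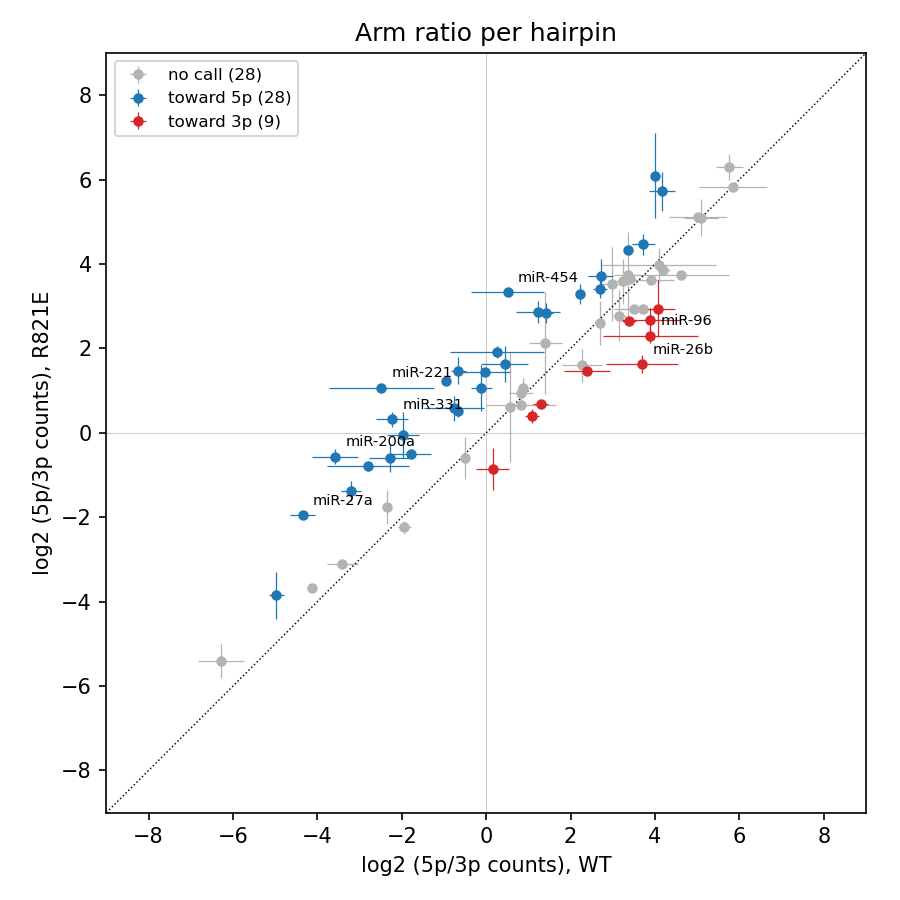
Log2 ratio of 5p to 3p counts for each of 65 hairpins in WT (x axis) and in R821E (y axis); points are means of 2 libraries, bars are SD and the dotted line marks equality. The 28 hairpins called toward 5p lie above the line and the 9 called toward 3p lie below it.

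R821E and R821A differ only in the residue that replaces this arginine, and the direct comparison asks whether that choice matters. R821E had 82 entries higher and 73 lower than R821A, and 1 higher and 189 lower on the spike-in scale, where the median was -1.06. miR-25-3p was lower by -1.94 ± 0.160 (edgeR, adjusted p = 4.15e-06), at 582 ± 24.8 against 2235 ± 103 CPM. The other leading falls with at least 100 CPM in either group were miR-3200-3p and miR-1915-3p, each with 4 counts in R821E against 55 and 52 in R821A (ratios 0.131 and 0.139, 95% exact counting intervals 0.0345 to 0.355 and 0.0364 to 0.377), miR-193a-3p (-1.78) and miR-877-5p (-1.77). The leading rises were miR-8072 (2.35, and 1.38 on the spike-in scale), miR-3607-3p (1.54), miR-6516-3p (1.52), miR-1275 (1.43) and miR-1246 (1.41). In the arm comparison 23 of 65 hairpins shifted toward 5p and 2 toward 3p, led by miR-221 (2.80), miR-200a (2.71), miR-454 (2.23), miR-27a (2.10) and miR-331 (2.09) on one side and miR-96 (-1.87) and miR-26b (-1.63) on the other. The miR-15/16 family was higher in R821E for 6 of 11 members and lower for none (7 and 0 adjusted over the list alone), with a median of 0.85 that flipped to -0.16 on the spike-in scale (camera adjusted p = 0.0435, and adjusted p = 0.196 with an estimated correlation). The 5p entries (50 higher, 22 lower) and 3p entries (16 higher, 45 lower) parted as against WT (Fisher's exact test, p = 8.11e-07), with camera adjusted p = 0.010 and 1.22e-05 that became adjusted p = 0.186 and 0.110 with an estimated correlation. The 5p median of 0.22 flipped to -0.31 with total counts and -0.75 on the spike-in scale, while the 3p median was negative under every scaling. The 155 calls became 81 without R821E replicate 1, 87 without R821E replicate 2 and 97 without R821A replicate 1, the arm calls 16 without R821A replicate 1 and 7 among the 13 hairpins with at least 100 counts in both arms, and the split 19 higher and 132 lower with total counts and 61 and 82 with upper quartile factors.

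R821A changed few miRNAs, mostly of the let-7 family, whose members repress RAS, HMGA2 and LIN28. In R821A, 1 entry rose and 11 fell against WT, and on the spike-in scale 1 rose and 16 fell. miR-98-5p, a let-7 member, fell by 1.88 ± 0.302 (edgeR, adjusted p = 0.00233), from 762 ± 255 to 206 ± 8.16 CPM. let-7i-5p fell by 0.97 ± 0.141 (edgeR, adjusted p = 0.00161), from 6053 ± 976 to 3093 ± 46.0 CPM. let-7d-5p (-1.72), let-7e-5p (-1.34), let-7i-3p (-1.17), let-7f-5p (-0.90) and let-7a-5p (-0.74) fell as well. Beyond let-7, miR-185-5p (-1.42), miR-744-5p (-1.07), miR-101-3p (-0.95) and miR-25-3p (-0.76) fell, and miR-31-3p rose by 0.87 ± 0.124 (edgeR, adjusted p = 0.00161). Of 19 let-7 entries 7 fell and none rose, over all entries and adjusted over the list alone, with a median of -0.57 that was negative under every scaling (camera adjusted p = 2.02e-08, and adjusted p = 0.242 with an estimated correlation). Group II let-7 (5 lower of 13) had camera adjusted p = 9.86e-07 and group I (1 lower of 3) 0.0301, both also with adjusted p = 0.242 with an estimated correlation. Members of the let-7 family differ at few positions, and how reads shared between them were counted is not given in the sources used here, so single members are uncertain. No hairpin changed its arm ratio by limma, with 7 of 65 at unadjusted p under 0.05, 2 calls without WT replicate 2 and 3 calls among the 13 hairpins with at least 100 counts in both arms. The arm shift of R821E was larger by the direct test given above. The 12 calls became 2 without R821A replicate 1 and, when only the 4 libraries compared were fitted, 0 by edgeR, against 15 by DESeq2 on all libraries (3 higher, 12 lower).

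In E5, 9 entries rose and 25 fell, and on the spike-in scale 0 rose and 120 fell. The falls again included let-7 members and miR-185-5p, which fell by 1.62 ± 0.257 (edgeR, adjusted p = 0.00199) from 562 ± 135 to 182 ± 21.7 CPM. miR-98-5p (-1.75), let-7d-3p (-1.74), miR-744-5p (-1.43), miR-324-5p (-1.41), miR-1180-3p (-1.39), miR-454-3p (-1.33), miR-301a-3p (-1.28), let-7d-5p (-1.24) and let-7e-5p (-1.24) were the other leading falls with at least 100 CPM in either group. The abundant pair miR-221-3p (-0.92 ± 0.142, edgeR, adjusted p = 0.00199) and miR-222-3p (-0.50) fell, while miR-21-5p (0.25 ± 0.158), miR-31-5p (0.17 ± 0.221) and miR-27a-3p (-0.04 ± 0.218) did not pass on the TMM scale, and of these 3 miR-27a-3p was lower on the spike-in scale (-0.67, adjusted p = 0.0193). The rises with at least 100 CPM in either group were miR-3687 (1.47 ± 0.333, edgeR, adjusted p = 0.0186), miR-16-1-3p (0.85), miR-7974 (0.84), miR-1260b (0.71), the HOXB-encoded miR-10a-5p (0.71), miR-28-5p (0.56), miR-29b-1-5p (0.56) and miR-100-5p (0.51). The ninth, miR-663b, at 68.2 CPM in E5 and 17.9 in WT, rose most (1.89 ± 0.475, edgeR, adjusted p = 0.0264), and is named after its value was seen. So are 2 scarcer falls, miR-340-3p (-1.80 ± 0.448, edgeR, adjusted p = 0.0264) and miR-421, with 3 counts in E5 and 26 in WT (ratio 0.151, 95% exact counting interval 0.0292 to 0.492). None of the 9 rises passed on the spike-in scale, where the signs of miR-28-5p (-0.07), miR-29b-1-5p (-0.07) and miR-100-5p (-0.11) flipped.

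Of 19 let-7 entries in E5, 7 fell and none rose, and of 13 in group II, 6 fell, with medians of -0.37 and -0.64 that were negative under every scaling (camera adjusted p = 8.47e-04 for each, and adjusted p = 0.350 with an estimated correlation). The entries overlapping snoRNA, tRNA or rRNA had 2 rises and no fall of 9 (camera adjusted p = 0.0271), with a median of 0.63 on the TMM scale and 0.00 on the spike-in scale. The 3p entries, 14 lower and 1 higher of 148, had camera adjusted p = 0.0271. Both of these lists had adjusted p = 0.350 with an estimated correlation. Adjusted over the list alone, the counts of these 4 lists were as given. In group I let-7, 1 of 3 fell, and the median (0.19) and mean (-0.27) differed in sign. The miR-454 hairpin was the only hairpin that shifted, toward 5p by 1.85 ± 0.379 (limma, adjusted p = 0.0444). It rested on single libraries: 0 hairpins were called by limma without WT replicate 2, E5 replicate 1 or E5 replicate 2, and 3 without WT replicate 1, with 11 of 65 at unadjusted p under 0.05 in the full fit. It gave way to 0 calls with at least 5 counts in both arms, with the weaker arm at 20 counts in WT (chosen after the data were seen) and when only 4 libraries were fitted. There were 3 calls with at least 100 counts and 4 with a pseudocount of 5. The 34 calls became 0 when only the 4 libraries compared were fitted, 15 without WT replicate 2, 21 without E5 replicate 1 and 6 without E5 replicate 2, the 120 spike-in calls became 67 without E5 replicate 2, and the split was 3 higher and 28 lower with total counts and 13 and 22 with the DESeq2 size factors.

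On the TMM scale E5 and A5 were not shown to differ for any miRNA. There edgeR called 0 of 374 entries, with 37 at unadjusted p under 0.05 and 0 calls by DESeq2 and by limma-voom, and on the spike-in scale miR-25-3p (-0.84) and miR-92a-3p (-0.67) were lower in E5. The closest to a call was miR-25-3p, lower in E5 by -0.66 ± 0.147 (SE), with a 95% interval from -0.98 to -0.35 (edgeR, adjusted p = 0.190). For miR-185-5p the difference was -0.60, with an interval from -1.17 to -0.02 before adjustment, and for let-7e-5p -0.68, from -1.20 to -0.15. Of the 34 entries called in E5 against WT, the unadjusted interval of E5 minus A5 included 0 for 21. These entries were picked by the same E5 libraries, which inflates the difference in the direction of the pick. Over all tested entries the median interval was 1.42 log2 units wide. The let-7 family (15 of 19 members lower in E5, none called) had camera adjusted p = 0.0365 and its group II 0.0262, and both had adjusted p = 0.886 with an estimated correlation; the family median of -0.28 was negative on the spike-in scale too (-0.43). limma called 0 hairpins, with 1 of 65 at unadjusted p under 0.05, and 2 of the 13 with at least 100 counts in both arms. Without E5 replicate 1 there was 1 call by edgeR on either scale, and the 2 spike-in calls became 0 without E5 replicate 2, A5 replicate 1 or A5 replicate 2, and 0 without the spike-ins' own TMM factor.

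A5 and ΔPAZ helix each had a single miRNA past the test. In A5 miR-221-3p fell by 0.77 ± 0.141 (edgeR, adjusted p = 0.0336), from 25372 ± 2283 to 14835 ± 1435 CPM, and in ΔPAZ helix miR-25-3p fell by 0.92 ± 0.146 (edgeR, adjusted p = 0.00885), from 3778 ± 436 to 2001 ± 57.8 CPM. Against the spike-ins the counts were 60 lower and 18 lower, and none higher, and the 18 of ΔPAZ helix became 49 without the spike-ins' own TMM factor. The other abundant entries in A5 were miR-21-5p at 0.20 ± 0.158, miR-222-3p at -0.30 ± 0.135, miR-31-5p at -0.08 ± 0.221 and miR-27a-3p at -0.18 ± 0.218, and in ΔPAZ helix miR-21-5p at 0.25 ± 0.158, miR-222-3p at -0.03 ± 0.135, miR-31-5p at -0.06 ± 0.221, miR-221-3p at -0.50 ± 0.141 and miR-27a-3p at -0.21 ± 0.218, none of which passed on the TMM scale. On the spike-in scale miR-222-3p (-0.76, adjusted p = 0.00307) and miR-27a-3p (-0.64, adjusted p = 0.0440) were lower in A5 and miR-221-3p (-0.86, adjusted p = 0.00398) in ΔPAZ helix. Adjusted over the list alone, 4 of 19 let-7 entries in A5 and 1 in ΔPAZ helix were lower, against none over all entries, and no list passed camera in either mutant. In ΔPAZ helix the let-7 median (0.03) and mean (-0.07) differed in sign. miR-29c shifted toward 5p in ΔPAZ helix (1.26 ± 0.230, limma, adjusted p = 0.0173), and its call was lost without WT replicate 1 or either ΔPAZ helix library. It was also lost with at least 5 counts in both arms and when only 4 libraries were fitted. limma called 0 hairpins in A5, with 5 of 65 at unadjusted p under 0.05, 2 without WT replicate 1, 1 with at least 100 counts in both arms and 1 with a pseudocount of 5. The count for A5 became 8 without WT replicate 1, 4 without WT replicate 2 and 0 without A5 replicate 1 or A5 replicate 2, with 52 entries at unadjusted p under 0.05 and 2 calls by DESeq2. The call of miR-221-3p in A5 was also lost with upper quartile factors (adjusted p = 0.122), with only entries of at least 100 CPM (0.0540), without the robust step (0.0716) and when only 4 libraries were fitted (0.498), all by edgeR. It was lost with the replicate number as a block too. The count was 3 with no filter. For ΔPAZ helix the count became 6 without WT replicate 1, 5 without WT replicate 2 and 0 without ΔPAZ helix replicate 1 or 2, with 44 entries at unadjusted p under 0.05 and 3 calls by DESeq2. It was 0 when only 4 libraries were fitted (miR-25-3p, adjusted p = 0.398, edgeR) and 7 with no filter. On the spike-in scale the count of A5 became 1 without A5 replicate 1 and 16 without A5 replicate 2, that of ΔPAZ helix 1 without either of its libraries, and that of R821A 9 without R821A replicate 1.

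Some miRNAs were called lower in several mutants, which all share the same 2 WT libraries. miR-25-3p fell in 4 of the 5 mutants, all but A5 (-0.35), and let-7d-5p, let-7e-5p, let-7f-5p, let-7i-3p, let-7i-5p, miR-185-5p, miR-221-3p, miR-744-5p and miR-98-5p fell in 3. In 100 simulations of unchanged groups against shared WT libraries, lists of the same lengths had 3.19 entries in at least 3 mutants on average and at most 7, against the 10 observed, and 33 of the simulations had an entry in at least 4, as observed for miR-25-3p. The simulations drew each entry independently with one spread for all groups, whereas WT replicates differed most and let-7 members may share reads. Simulated counts may thus be too low, and the excess is not established. On the spike-in scale 11 entries fell in all 5 mutants: let-7e-5p, let-7i-3p, let-7i-5p, miR-101-3p, miR-1307-5p, miR-185-5p, miR-221-3p, miR-25-3p, miR-324-5p, miR-744-5p and miR-98-5p. The simulated lists of those lengths had 2.30 entries in all 5 on average and at most 5. These simulations held no fall common to all entries, unlike the observed values on the spike-in scale. Such a fall could by itself make the same well-measured entries recur, so the excess does not show a loss particular to these miRNAs. In GENCODE v29 on GRCh38 (hg38), MIR25 lies in an intron of MCM7 on chromosome 7 (100093560 to 100093643, minus strand), with the hairpin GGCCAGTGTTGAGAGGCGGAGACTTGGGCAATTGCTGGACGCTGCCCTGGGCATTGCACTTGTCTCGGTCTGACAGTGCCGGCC. MIR185 lies in an intron of TANGO2 on chromosome 22 (20033139 to 20033220, plus strand), with the hairpin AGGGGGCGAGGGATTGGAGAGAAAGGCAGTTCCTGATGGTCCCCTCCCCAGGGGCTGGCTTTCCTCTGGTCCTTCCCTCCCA. MIR221 lies in an intron of the long noncoding gene MIR222HG on chromosome X (45746157 to 45746266, minus strand), MIR98 in an intron of HUWE1 on chromosome X (53556223 to 53556341, minus strand), MIR744 in an intron of MAP2K4 on chromosome 17 (12081899 to 12081996, plus strand), and MIRLET7I on chromosome 12 (62603686 to 62603769, plus strand). MIR8072, the source of the entry that rose on both scales in R821E, overlaps an exon of SBNO1 on chromosome 12 (123364764 to 123364843, minus strand).

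**Figure D4:**
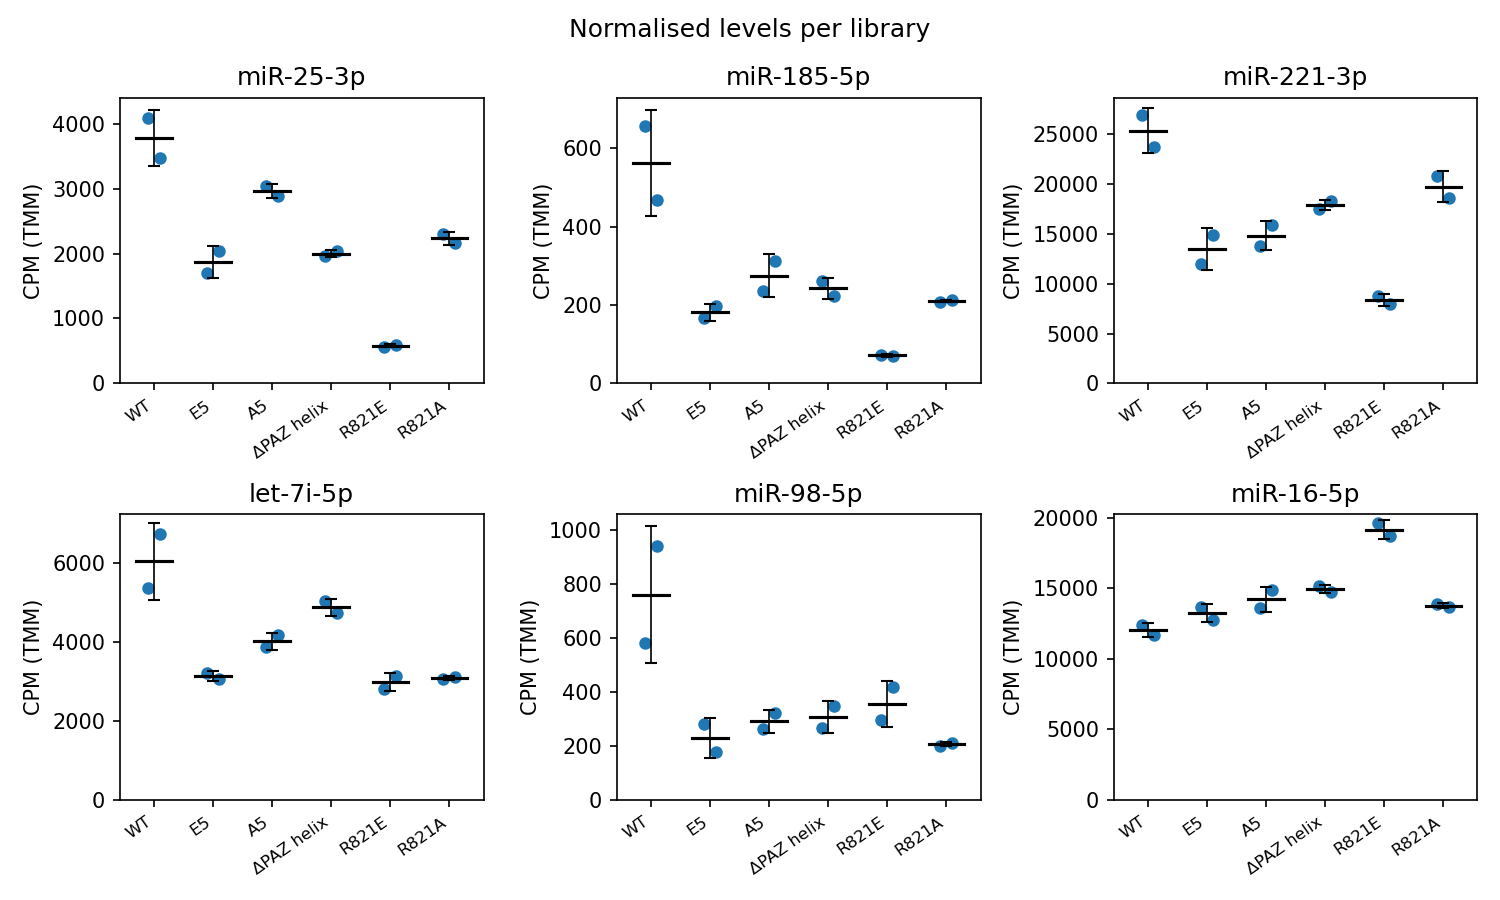
TMM-normalised counts scaled to library size (CPM) of 6 miRNAs in each library (points), with group means (lines) and SD (error bars, n = 2). miR-25-3p is lowest in R821E (582 CPM against 3778 in WT), and miR-16-5p is higher in R821E than in WT on this scale (19158 against 12048) but not on the spike-in scale, where its log2 fold change is -0.59.

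The fold changes of the 5 mutants were correlated across miRNAs, in part because all share the same WT libraries. Pearson's r ran from 0.44 for R821E with R821A to 0.66 for ΔPAZ helix with R821E over the 10 pairs, against mean simulated values of 0.43 to 0.49 for unchanged groups. In 4 pairs r lay above the highest of 100 simulated values (E5 with R821E, A5 with ΔPAZ helix, A5 with R821E and ΔPAZ helix with R821E). In the other 6 it did not, as for E5 with A5 (0.61, simulated highest 0.63) and R821E with R821A (0.44, simulated mean 0.44). The covariance of the 10 pairs ran from 0.13 to 0.40, and in 8 it lay above the highest simulated one. That of E5 with R821E was 0.40 against a simulated mean of 0.087 and highest of 0.14, and that of R821E with R821A 0.23 against 0.087 and 0.14. A5 with R821A (0.135, simulated highest 0.141) and ΔPAZ helix with R821A (0.132, simulated highest 0.144) did not exceed it. miRNAs are not independent replicates, and no p-value was computed for these 10 relations. The simulations drew entries independently, with one spread per entry for all groups. WT replicates differed most, with an SD of their log2 difference of 0.643 against 0.446 to 0.604 in the mutants. Simulated values may thus be too low, here and for the shared calls below, and pairs near the simulated highest stay undecided. For the falls, E5 and R821E shared 23 entries, against 6.02 for independent lists and a mean of 14.0 (highest 19) for lists of the same lengths from the 100 simulations with shared WT libraries. R821E and R821A shared 11 (2.65 if independent, simulated mean 6.52 and highest 10) and E5 and R821A 9 (0.735 if independent, simulated mean 3.32 and highest 7). E5 and R821E shared 9 rises (2.14 if independent), which did not exceed the simulated highest of 9 (mean 6.44). The WT libraries were not divided between comparisons here, since each part would hold 1 library, and part of each overlap may come from them.

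No list of miRNAs known from other cell types passed camera in any comparison. In R821E the erythroid list had 1 of 3 higher (miR-451a), the leukocyte list 1 of 3 lower (miR-142-3p, -0.91), the neuronal list 2 of 4 higher (miR-9-5p, 1.30, and miR-128-1-5p, 1.64) and 1 lower (miR-128-3p, -1.51), and the list of fibroblasts and endothelium 2 of 5 lower (miR-126-3p, -1.70, and miR-145-5p, -0.84). In the other mutants edgeR called none of these against WT over all entries, and adjusted over the list alone 2 neuronal entries were higher and 1 lower in E5 and 1 was lower in A5. No member of the muscle and hepatocyte lists or of the embryonic miR-371 to miR-373 and miR-302 clusters was abundant enough to be tested.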

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

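The spike-in scale, the tests of spike-in amount, of loss of the dominant arm, of the WT libraries as cause, of library preparation and of a sample swap were chosen only after the results were seen; the thinning test was chosen before.

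The spike-in sequences, which the comparisons on the TMM scale do not use, took a larger mean share of counts in every mutant than the 3.99% of WT: 5.52% in E5, 5.13% in A5, 4.97% in ΔPAZ helix, 6.54% in R821E and 4.91% in R821A. The 9 entries overlapping snoRNA, tRNA or rRNA lay above the other tested entries on the spike-in scale by a median of 0.63 in E5, 0.46 in A5, 0.45 in ΔPAZ helix, 1.32 in R821E and 0.38 in R821A (log2). On the TMM scale the differences were 0.62, 0.46, 0.44, 1.31 and 0.38, since a change of scale moves all entries of a library alike, so they describe composition and decide nothing about amounts. On the spike-in scale the 9 had medians of 0.00 (E5), -0.01 (A5), 0.09 (ΔPAZ helix), -0.07 (R821E) and 0.09 (R821A). The others had -0.63, -0.47, -0.36, -1.38 and -0.29. An unequal amount of spike-in or of RNA would move both alike, so it cannot make the gap between them. For the same reason the gap cannot show whether the amounts differed. Beside a change of composition, an unequal amount cannot be told apart from a lower output of miRNAs by the mutant enzymes. No value here measures the RNA added to each library, and the 9 entries are not known to be unchanged. A different level of the rescue protein, which was not measured here, stays open too.

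Hairpins shifted toward their 5p arm in R821E by a median of 0.54 (log2), which a loss of whichever arm is dominant could produce in hairpins led by 3p. That explanation predicts no shift for a hairpin with equal arms, but the regression of the shift on the R821A ratio had an intercept of 0.79 ± 0.140 (SE, 65 hairpins). The slope was -0.194 ± 0.0464 (SE), so the shift did fall with the ratio, as that explanation predicts. It is thus argued against as the whole account and not as a part. Lower depth was argued against by thinning every library to 154846 counts, which left a median of 0.45 (26 toward 5p, 5 toward 3p), and a peculiarity of WT alone by the comparison with R821A, where the median was 0.47 and 47 of 65 hairpins shifted toward 5p (exact sign test, two-sided, p = 4.22e-04, hairpins not independent). R821A replicate 1 shared the deviation of WT replicate 1 given below, so this comparison cannot exclude a peculiarity common to WT and R821A. GC content and end sequence of the arms, which can bias ligation and amplification, were not tested for this shift and stay open, as does an effect of the mutation on how arms are cut or retained.

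WT replicate 1, E5 replicate 2 and R821A replicate 1 deviated from their partners in a shared way, with a mean correlation of deviations of 0.38 over miRNA entries. The spike-in sequences, which do not come from the cells, showed it too, with a mean r of 0.48 over 29 sequences (0.55, 0.58 and 0.30 for the 3 pairs; one-sided permutation p = 1e-05, the smallest the permutations can give). That is consistent with a difference in library preparation. A swap of WT replicate 1 with E5 replicate 2 would turn the sign of their difference, but E5 replicate 2 minus WT replicate 1 went the same way as E5 replicate 1 minus WT replicate 2, with r = 0.52 and Spearman's rho = 0.51 over 374 entries (one-sided permutation p = 1e-04, the smallest the permutations can give, entries not independent). The design gives no group that follows this split, so no biological explanation was tested. These 3 libraries were named after the correlations of deviations between groups were seen, so the 0.38 over miRNA entries is a selected value. By replicate number, ΔPAZ helix correlated at -0.24 with WT, near the -0.26 of E5 with R821A, but at 0.10 with E5 and -0.04 with R821A. ΔPAZ helix was not part of the spike-in test.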

How the results depend on the processing

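The spike-in scale, leaving out miR-21-5p or entries without an arm, the minimum on the weaker arm in WT and crossed replicate numbers were chosen only after the results were seen; the other alternatives were planned.

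Among named entries, 1465 values under an alternative kept direction and side of the threshold, 228 no longer passed, 9 newly passed and 28 reversed, and among counts, list tests and correlations 201 stayed close, 100 moved, 5 lost and 1 gained a call. Small folds would mostly be missed with these libraries, as the simulated recovery shows. Depth was not varied in it, and the spread between replicates lay above counting error. With 2 libraries per group a single library decides many counts. Where no cause is named, the cause was not tested.

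For entries changed, A5 against WT (1) gave 0 with upper quartile factors, 2 with total counts, 3 with no filter, 0 with at least 100 CPM, 0 without the robust step, 0 at 2-fold or more, 0 with only 4 libraries, 2 with DESeq2, 60 on the spike-in scale, 3 without miR-21-5p and 4 without entries that name no arm. ΔPAZ helix against WT (1) gave 3 with total counts, 7 with no filter, 2 with at least 100 CPM, 0 at 2-fold or more, 0 with only 4 libraries, 3 with DESeq2, 18 on the spike-in scale and 4 without entries that name no arm. E5 against WT (34) gave 15 at 2-fold or more, 0 with only 4 libraries and 120 on the spike-in scale. R821A against WT (12) gave 6 at 2-fold or more and 0 with only 4 libraries, R821E against R821A (155) gave 89 at 2-fold or more, and E5 against A5 (0) gave 2 on the spike-in scale. A fit of 4 libraries has fewer degrees of freedom by construction and takes its spread from the groups compared alone. A fold minimum can only remove calls. The fit over all 12 libraries shares its spread between groups that differed in noise. The chi-square of replicate counts per degree of freedom was 29.4 in WT, 16.1 in E5 and 3.98 in ΔPAZ helix. Shared-fit p-values against WT can thus be too small, and what each of these adds to the lost calls was not tested. Without the TMM factor of the spike-ins, ΔPAZ helix gave 49 in place of 18 and E5 against A5 gave 0 in place of 2.

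For the arm ratio, E5 (1) gave 3 with at least 100 counts, 0 with at least 5 counts, 4 with a pseudocount of 5, 0 with the weaker arm at 20 counts in WT and 0 with 4 libraries. A5 (0) gave 1 with at least 100 counts and 1 with a pseudocount of 5, ΔPAZ helix (1) gave 0 with at least 5 counts and 0 with 4 libraries, R821E (37) gave 9 with at least 100 counts and 24 with 4 libraries, R821A (0) gave 3, E5 against A5 (0) gave 2 and R821E against R821A (25) gave 7 with at least 100 counts, where only 13 hairpins were tested. For lists, an estimated correlation gave 0 calls for E5 (3), R821A (3), E5 against A5 (2) and R821E against R821A (1), and fry gave 1 for A5 (0), 11 for R821E (0), 0 for R821A, 0 for E5 against A5 and 9 for R821E against R821A. The 3p list in E5 had adjusted p = 0.350 with an estimated correlation and 0.101 by fry, the 5p list in R821E 0.00556 by fry, the 3p list in R821E 0.147 with an estimated correlation, and R821E against R821A 0.186 (5p) and 0.110 (3p) with an estimated correlation. Among the 250 entries with at least 100 CPM, correlations of effects were 0.675 (E5 and A5), 0.668 (E5 and ΔPAZ helix), 0.678 (E5 and R821E), 0.624 (E5 and R821A), 0.80 (A5 and ΔPAZ helix), 0.721 (A5 and R821E), 0.712 (A5 and R821A), 0.785 (ΔPAZ helix and R821E), 0.676 (ΔPAZ helix and R821A) and 0.530 (R821E and R821A), each above its value over all 374. The simulated values cover all 374 entries only, so these correlations, which share the WT libraries too, have none to be read against.

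Directions reversed for miR-27a-3p in E5 (0.011 with the DESeq2 size factors and 0.011 with DESeq2). On the spike-in scale they reversed in E5 for miR-28-5p (-0.070), miR-29b-1-5p (-0.073), miR-100-5p (-0.11), miR-21-5p (-0.39) and miR-31-5p (-0.46), for miR-21-5p in A5 (-0.27), ΔPAZ helix (-0.11), R821E (-0.25) and R821A (-0.22), and for miR-222-3p in R821A (-0.11), since that scale moves every entry by the same shift per library.

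Leaving out each library in turn gave these lowest and highest counts. Entries changed were 6 (without E5 replicate 2) to 28 in E5, 0 to 8 in A5, 0 to 6 in ΔPAZ helix, 2 (without R821A replicate 1) to 16 in R821A, 0 to 1 for E5 against A5 and 81 to 108 for R821E against R821A. The maxima of 8 and 6 were both without WT replicate 1. On the spike-in scale they were 67 to 125 in E5, 1 to 56 in A5, 1 to 25 in ΔPAZ helix, 9 to 18 in R821A and 0 to 1 for E5 against A5. Hairpins shifted were 0 to 3 in E5, 0 to 2 in A5, 0 to 1 in ΔPAZ helix, 18 to 34 in R821E, 0 to 2 in R821A and 16 to 25 for R821E against R821A. Signs on the TMM scale changed for entries that did not pass on that scale, of which miR-27a-3p in E5 and A5 and miR-31-5p in R821E were lower on the spike-in scale: miR-27a-3p ran from -0.38 to 0.30 in E5, -0.52 to 0.10 in A5, -0.53 to 0.085 in ΔPAZ helix and -0.43 to 0.18 in R821A; miR-31-5p from -0.18 to 0.61 in E5, -0.49 to 0.30 in A5, -0.45 to 0.34 in ΔPAZ helix, -0.71 to 0.080 in R821E and -0.64 to 0.15 in R821A; miR-222-3p from -0.20 to 0.066 in ΔPAZ helix and -0.00342 to 0.29 in R821A; and miR-21-5p from -0.093 to 0.16 in R821A. A group left with 1 library is assumed to vary like the others.

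With the replicate number as a block, entries changed were 22 in E5, 0 in A5, 1 in ΔPAZ helix, 171 in R821E, 12 in R821A, 0 for E5 against A5 and 148 for R821E against R821A, and the block changed no list call. Same-numbered deviations from the group means correlated at -0.50 (WT and E5), -0.10 (A5), -0.24 (ΔPAZ helix), -0.12 (R821E) and 0.37 (R821A) with WT, so the numbers do not pair the samples. Crossed pairing gave 35 in E5, 1 in ΔPAZ helix and 174 in R821E.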

Other observations

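Both hypotheses below, on GC content and on clusters, and their tests were chosen before their results were seen.

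In R821E the fall was larger for miRNAs of GC-rich hairpins. Across entries, Spearman's rho between hairpin GC content and the log2 fold change against WT was -0.32 for 5p entries (166 of 174 with a value) and -0.39 for 3p entries (146 of 148), each with a one-sided permutation p of 1e-04, the smallest the permutations can give, and 0.00104 after Benjamini-Hochberg adjustment of two-sided p over the 26 relations computed. Entries are not independent replicates. In E5 rho was -0.31 and -0.27 (adjusted permutation p = 0.00104 and 0.00455), in ΔPAZ helix -0.20 and -0.14 (0.0246 and 0.186), in A5 -0.09 and -0.11 (0.353 and 0.323) and in R821A -0.04 and 0.05 (0.679 and 0.665). The direct comparisons gave -0.37 and -0.43 for R821E against R821A (0.00104 each) and -0.29 and -0.22 for E5 against A5 (0.00173 and 0.0208). Of 12 such relations between replicates of one group, 2 passed (-0.22 for 5p entries in R821E, 0.0133, and 0.26 for 3p entries in R821A, 0.00455), their signs set only by which replicate is numbered 1, and the other 10 did not (adjusted p from 0.0862 to 0.991). A GC bias of library preparation was not tested further and stays open beside a dependence of the mutant enzymes on hairpin sequence.

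Hairpins that share a primary transcript might be expected to move together. In R821E the 5p entries of 17 clusters (50 entries, 66 pairs, hairpins within 10 kb) differed by 0.85 log2 on average within a cluster against 1.02 for random pairs (one-sided permutation p = 0.0842), which leaves this undecided. In 1 of these pairs, miR-500a-5p and miR-500b-5p, the counts are identical, which lowers the average within clusters. The largest clusters, of 7 and 6 entries, give the most pairs and so weigh most.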
